A study of Komagataella phaffii GS115 with 6 samples.

How the data were processed

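RNA-seq libraries were made from the methylotrophic yeast Komagataella phaffii (Pichia pastoris) strain GS115, grown for 48 h in BMMY, a buffered complex medium with methanol as carbon source, or in BMMY with 1% maltose. There were 3 libraries per medium, 6 in all, and the sample labels gave each library its medium and replicate number. Total RNA was extracted with a commercial kit and libraries were prepared with an mRNA isolation kit, per the labels' protocols. CASAVA, HISAT2 2.2.1 and StringTie are named, with no role or order, per the submitters' processing notes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed.

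The table analysed here holds 115 genes. For each gene and library it holds whole-number read counts, per the file headers. It also holds FPKM values for each library, deposited by the authors, which are counts scaled by gene length and by the number of fragments in the library. For each gene the authors deposited a p-value of their own comparison, whose test and adjustment are not given in the sources used here. The authors also deposited a log2 fold change per gene, positive where the maltose libraries were higher. All 115 genes had an absolute log2 fold change of at least 1.0 in the authors' deposited table, 56 positive and 59 negative, and the largest p-value in the authors' deposited table was 0.0465. The genes had therefore been selected on these same 6 libraries. Counts of genes past a threshold are shares of a selected list, their p-values are not independent evidence of a difference, and other genes of the genome were not analysed here.

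Gene symbols came from the Swiss-Prot annotation in the same table, so some are names of similar proteins in other species. A symbol was present for 86 genes, 87 had a symbol or a description and 28 had neither. All 115 identifiers matched the 5040 genes of the RefSeq annotation of assembly ASM2700v1, which was used only for product names, gene lengths and gene order. Of its gene lengths 92.2% are multiples of 3, so most were taken to be coding lengths.

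Because totals over all genes were needed, the depth of each library was worked out from the deposited counts and FPKM values, as the median over genes of count divided by FPKM and gene length. The implied totals ran from 35.3 to 76.1 M fragments. Their ratios between libraries are better fixed than their absolute size, which depends on the gene lengths used. The lowest count of any listed gene in a library was between 11 and 31, and depth bears on counting error only.

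Before the data were examined, the test had been set as limma on log2(FPKM + 1), with edgeR's quasi-likelihood test to take its place if the table held counts. The table held counts, so edgeR 4.0.16 in R 4.3.3 was used, with group as the only term and the implied depths as library sizes. No TMM factors were used, since a list selected for change cannot serve as its own reference. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which kept 112 and left out 3. P-values are two-sided and adjusted by the Benjamini-Hochberg method over those 112 genes, with a threshold of 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. Fold changes are maltose over BMMY. Means and SDs are of FPKM with n = 3 libraries per group. The procedure was tested on simulated counts for 112 genes, where it called 16 of 20 genes changed by 1 on the log2 scale, 20 of 20 changed by 2, and 1 of 72 unchanged genes. The simulated genes were independent, shared a common dispersion and were mostly unchanged. The real list was selected for change, so these rates need not hold for it.

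The genes named were fixed by a rule before the data were examined. It takes the 10 largest positive and 10 largest negative log2 fold changes among named or described genes that passed the threshold and whose groups did not overlap. It adds up to 4 called members of each of 30 gene lists, and every listed gene for methanol or maltose use. Genes named outside this rule were chosen after their values were seen, and are said to be so. The lists were keyword searches on symbols and products. After the data were examined, 3 wrong matches were dropped: MXR1 (here a peptide methionine sulfoxide reductase) from methanol use, ARO10 (a phenylpyruvate decarboxylase) from glycolysis, and YPS1 (a membrane-anchored protease) from sterols and lipids. For lists with at least 3 called members, the split between higher and lower was compared with that of the other called genes by a two-sided Fisher's exact test, adjusted over the 4 lists tested.

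The scaling between libraries behind the deposited log2 fold changes was recovered by solving for 6 factors that turn the counts into those fold changes. Over 92 genes with counts of at least 200, the largest difference between recovered and deposited log2 fold changes was 0.0034. Alternatives set before the data were examined were no filter, a mean FPKM of at least 10, libraries brought to the same median or to the same FPKM sum over the listed genes, no trend in the prior variance, the replicate number as a block, each library left out in turn, a pseudocount of 0.1 with limma 3.58.1, stricter thresholds and the authors' own calls. Alternatives chosen after the data were examined were limma on log2(FPKM + 1), the recovered scaling, TMM factors, and DESeq2 1.42.0 for size factors and for the test. For the gene lists and the named genes, equal FPKM sums, the filter of 10 and no trend were also added then, as were the stricter thresholds for the lists and no filter for the named genes. The remaining steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.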

Results

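Transcript levels were measured by RNA-seq in Komagataella phaffii GS115 after 48 h in BMMY medium, in which methanol is the carbon source, and in BMMY with 1% maltose added. Each medium had 3 libraries. The series concerns maltose and the production of recombinant collagen in this yeast, and the comparison asks which transcripts differ when maltose is present. The sample labels give the cells as WT, and whether they carried a collagen construct is not known here. The values analysed here cover 115 genes that the authors had selected as changed. The counts over these genes were 5387551, 5708653 and 3655044 in BMMY replicates 1, 2 and 3, and 8244143, 6905696 and 5391269 in maltose replicates 1, 2 and 3. The depths implied by counts and FPKM were 53.2, 76.1 and 53.5 M fragments in BMMY and 55.3, 45.6 and 35.3 M with maltose. The listed genes took 10.13%, 7.5% and 6.83% of the implied depth in the BMMY libraries and 14.91%, 15.14% and 15.28% in the maltose libraries. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

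With maltose, an arginase gene (CAR1, PAS_chr2-2_0288), the proline oxidase gene PUT1 and the proline permease gene PUT4 were the most strongly lowered of the named genes, and TPN1 and THI5, with annotated roles in vitamin B6 uptake and thiamine synthesis, were the most strongly raised. The rule for named genes leaves out genes with no name or description, among them PAS_chr4_0058 and PAS_chr4_0064, which rose more than TPN1 and THI5. This CAR1 gene was 16.5-fold lower and THI5 (PAS_chr4_0065) was 4.1-fold higher. Of 112 genes tested, 105 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 49 higher and 56 lower with maltose. The list had been selected on these libraries, so this count is not independent evidence. The 7 genes that did not pass all had positive fold changes, and 5 of them have a symbol: ARO7, GLY1, SUT2, RCF2 and the flavin adenine dinucleotide synthetase gene PAS_chr1-3_0240 (named after their values were seen).

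The log2 fold changes in the authors' deposited table lie above the log2 FPKM ratios by a median of 0.36 (0.28 to 0.39). A list selected at 1.0 on the authors' scale therefore admits smaller rises than falls on the FPKM scale, where the smallest were 0.63 and -1.34, and the sizes of rises and falls are not compared here. The split of calls between higher and lower moved with the scaling: it was 56 and 56 with the authors' scaling, 56 and 35 with equal medians, 13 and 56 with TMM, and 7 and 56 with equal FPKM sums over the listed genes. Median log2 fold changes shifted by 0.36, 0.94, -0.49 and -0.86 under these scalings. With equal FPKM sums, 33 higher genes turned negative, none of them past the threshold, and no other scaling tried turned a direction. In the maltose libraries the higher genes held 14.72% to 15.06% of the implied depth, and the lower genes 0.18% to 0.21%. Equal FPKM sums therefore take out much of the rises by construction. Values under that scaling, here and below, show how a rise depends on scaling. They do not test single rises. Of the 20 named higher genes, 3 passed with equal FPKM sums (TPN1, THI5 and PAS_chr1-3_0151) and 8 with TMM (these and Gid4, THI73, THI4, thi4 and FDH1), while the 20 named lower genes all passed with both. Both of these scalings shift all fold changes downward, which favours falls. With equal medians, which shift them upward, all 20 named higher genes passed and 17 of the 20 named lower genes.

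BMMY replicate 1 stood apart from the other BMMY libraries. It lay above both of them in 47 of the 56 genes with positive fold changes and in 23 of the 56 lower genes. Over genes selected for a difference between the media, a first principal component that separates the media follows from the selection. That component held 90.1% of the variance of the tested genes, not of all transcripts. On it, BMMY replicate 1 was at -5.44, while BMMY replicates 2 and 3 were at -8.53 and -9.22. The maltose libraries were between 6.95 and 8.2. Without BMMY replicate 1, 112 of 112 genes passed, 56 in each direction. Without BMMY replicate 2 the higher genes numbered 29 in place of 49.

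**Figure D1:**
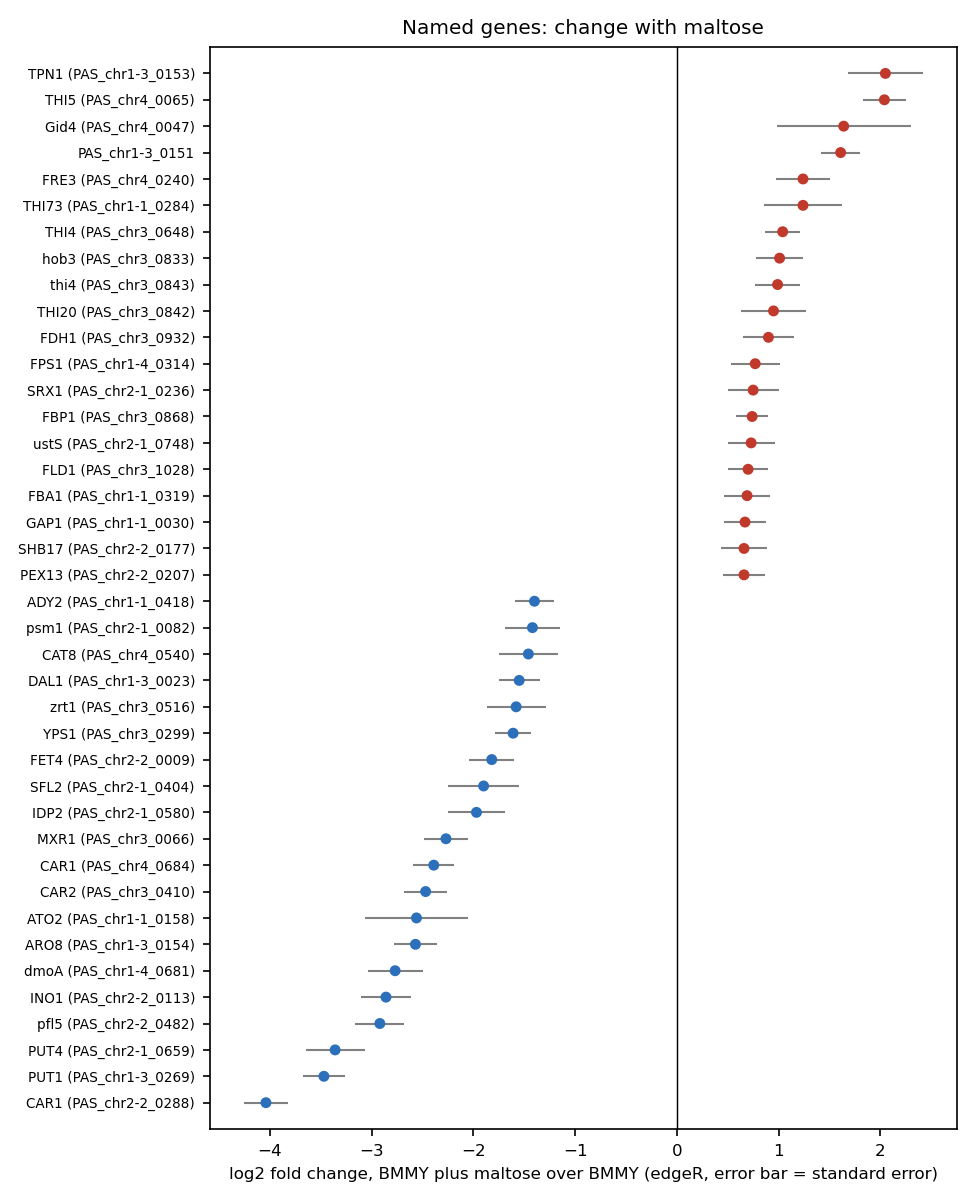
Log2 fold changes of the 40 named genes, maltose over BMMY, from edgeR's quasi-likelihood test on 3 libraries per medium, with standard errors as bars. Higher genes (red) run from 0.66 for PEX13 to 2.05 for TPN1 and lower genes (blue) from -1.4 for ADY2 to -4.04 for CAR1, and with equal FPKM sums SRX1, FBP1, FBA1, GAP1, PEX13, SHB17, ustS, FPS1 and FLD1 turn negative.

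Most listed genes of amino acid metabolism were lower with maltose. Of 15 members tested, 12 were lower, 1 was higher and 2 did not pass, and 13 passed when adjusted over the list alone. CAR1 (PAS_chr2-2_0288), an arginase, which splits arginine into ornithine and urea, fell from 396 ± 56.2 to 24.0 ± 2.83 FPKM (SD, n = 3), a log2 fold change of -4.04 (SE 0.22, adjusted p = 1.02e-05). PUT1 (PAS_chr1-3_0269), the mitochondrial proline oxidase, fell from 448.0 ± 54.4 to 40.5 ± 4.56 FPKM, 11.0-fold (adjusted p = 1.04e-05). PUT4 (PAS_chr2-1_0659), a proline permease rather than an enzyme, was 10.3-fold lower (57.3 ± 6.11 to 5.58 ± 1.97 FPKM, adjusted p = 4.05e-05). A gene with the symbol of the aromatic aminotransferase ARO8 (PAS_chr1-3_0154) was 5.93-fold lower (84.2 ± 16.0 to 14.2 ± 1.17 FPKM, adjusted p = 4.05e-05). CAR2 (PAS_chr3_0410), ornithine transaminase, and a second gene annotated as arginase (CAR1, PAS_chr4_0684) were 5.54-fold and 5.23-fold lower, each with an adjusted p of 4.05e-05. Whether reads were shared between the arginase genes was not tested. The higher member, AGX1 (PAS_chr4_0416, named after its value was seen), encodes alanine:glyoxylate aminotransferase and was 1.59-fold higher (adjusted p = 0.0165). It did not pass without BMMY replicate 2 (log2 0.59), BMMY replicate 3 (0.56) or maltose replicate 1 (0.63), and it turned to -0.17 with equal FPKM sums. ARO7 and GLY1 had adjusted p-values of 0.0667 and 0.068. The keyword search did not take in every related gene. CPA1 (PAS_chr4_0138), the small subunit of carbamoyl phosphate synthetase, was outside the list and 1.75-fold higher (adjusted p = 0.0195). The call for CPA1 was lost without BMMY replicate 2 (log2 0.68), BMMY replicate 3 (0.72) or maltose replicate 3 (0.57), and with equal FPKM sums CPA1 was at -0.02. ARO10 (PAS_chr3_0095), a phenylpyruvate decarboxylase, was also outside the list and 3.33-fold lower (adjusted p = 3.85e-04). Both were named after their values were seen. The list leaned further toward lower genes than the other called genes did (two-sided Fisher's exact test, p = 0.00248, adjusted p = 0.00994 over 4 lists). That call was lost in 9 of 20 alternatives, among them the fit without BMMY replicate 1, where ARO7 and GLY1 passed as higher (adjusted p = 0.119 for the list), and the fit with equal FPKM sums, where no member was higher (adjusted p = 0.329). Over the 20 the adjusted p ran from 8.31e-04 to 0.329. Each was adjusted over the lists with at least 3 called members in that alternative, often fewer than 4. With equal FPKM sums this list was the only one tested.

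Nitrogen and amino acid transport genes went both ways: of 3 members tested, 1 was higher and 2 were lower (adjusted Fisher's exact p = 1), and 3 passed when adjusted over the list alone. PUT4, given above, and DAL1 (PAS_chr1-3_0023) were lower. The keyword search did not match the methionine permease MUP1 (PAS_chr2-1_0351, named after its value was seen), which was 2.66-fold lower. DAL1 is allantoinase, an enzyme of allantoin breakdown and not a transporter, and was 2.93-fold lower (11.2 ± 1.05 to 3.82 ± 0.82 FPKM, adjusted p = 2.45e-04). GAP1 (PAS_chr1-1_0030), the general amino acid permease, was 1.59-fold higher (90.7 ± 8.78 to 144.0 ± 29.7 FPKM, adjusted p = 0.0165), but turned to -0.21 on the log2 scale with equal FPKM sums and did not pass without BMMY replicate 2 (0.59) or maltose replicate 3 (0.49).

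**Figure D2:**
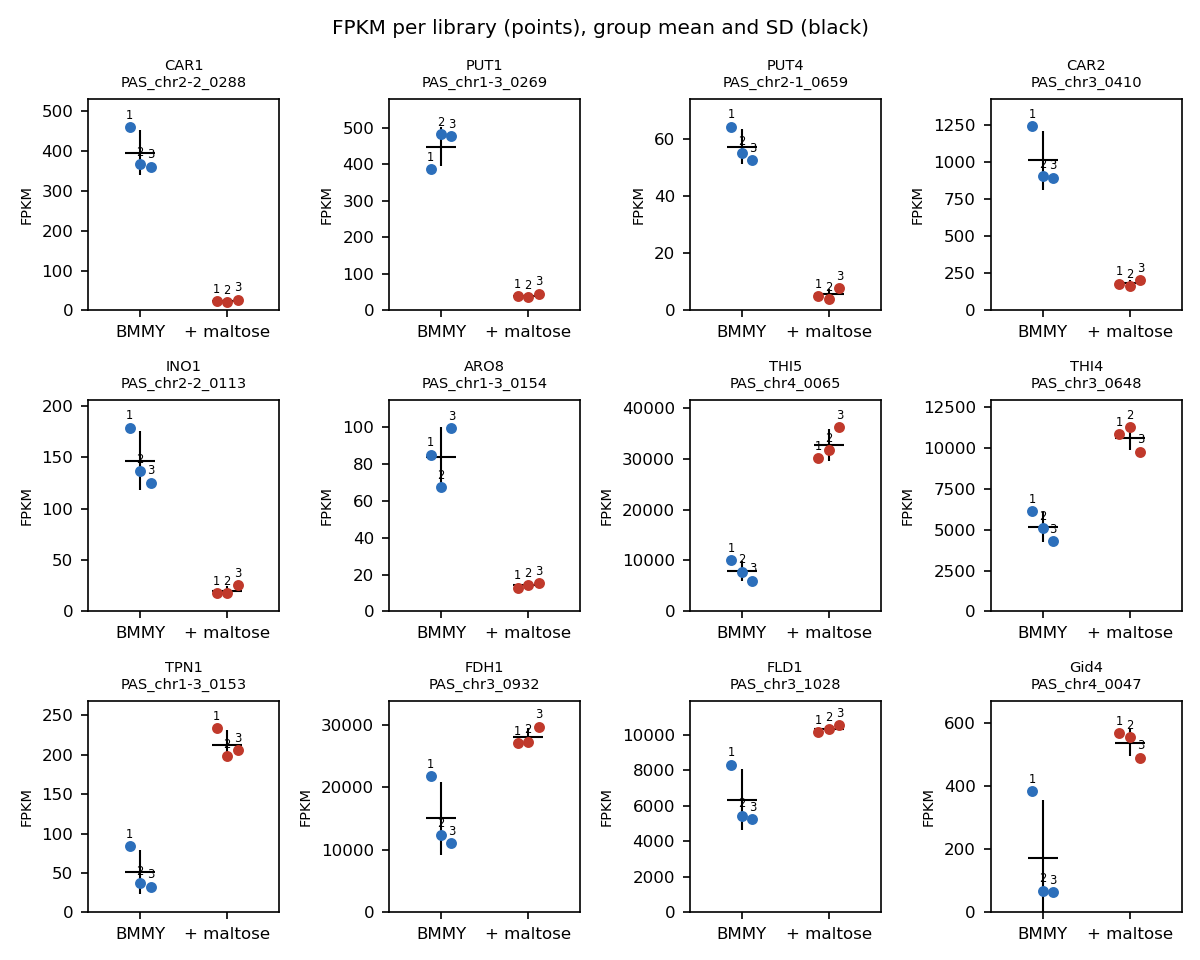
FPKM in each library (numbered points) for 12 named genes in BMMY (blue) and BMMY with maltose (red), with black lines for the mean and SD of 3 libraries. In CAR1 the BMMY mean was 396 and the maltose mean 24.0, and in Gid4 BMMY replicate 1 (385) lay far above replicates 2 (69.4) and 3 (64.0), so that its SD bar reaches the axis; FLD1 turns negative with equal FPKM sums.

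Several of the largest rises among named genes were in genes annotated for making or taking up vitamins. THI5 (PAS_chr4_0065), which acts in the synthesis of the pyrimidine part of thiamine, rose from 7952 ± 1992 to 32642 ± 3209 FPKM, a log2 fold change of 2.04 (SE 0.21, adjusted p = 8.76e-05). THI4 (PAS_chr3_0648), the thiazole synthase of the same pathway, rose 2.06-fold from 5173 ± 916.3 to 10631 ± 780.1 FPKM (adjusted p = 7.97e-04). A bifunctional thiamine enzyme, thi4 (PAS_chr3_0843), was 1.99-fold higher (adjusted p = 0.00301). THI20 (PAS_chr3_0842), a hydroxymethylpyrimidine kinase, was 1.93-fold higher (adjusted p = 0.0203), and this call was lost without BMMY replicate 2 (log2 0.79), BMMY replicate 3 (0.76) or maltose replicate 3 (0.79). TPN1 (PAS_chr1-3_0153), a plasma membrane transporter of vitamin B6, rose from 51.3 ± 28.4 to 212 ± 18.7 FPKM, 4.14-fold (adjusted p = 0.00128). THI73 (PAS_chr1-1_0284), a putative carboxylic acid permease, was 2.36-fold higher (adjusted p = 0.015), and did not pass without BMMY replicate 2 (log2 1.05) or maltose replicate 3 (1.0). With equal FPKM sums THI4 was at 0.19 on the log2 scale, thi4 and THI20 at 0.15 and THI73 at 0.45, none of them past the threshold, while THI5 (1.2) and TPN1 (1.26) passed. These genes were taken by the size of their change and not from a fixed list. BMMY replicate 1 held the highest BMMY value for each of them, for example 83.9 FPKM for TPN1 against 37.2 and 32.7.

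Both genes kept in the keyword list for methanol use were higher with maltose, 2 of 2 tested and 2 when adjusted over the list alone. MXR1 also matched the search and was 4.82-fold lower. As a peptide methionine sulfoxide reductase it was dropped from the list, after the data were examined. The deposited pathway annotation places FBP1 and AGX1 with the 2 kept genes under methane metabolism, so the keyword list need not hold every gene of methanol use. FDH1 (PAS_chr3_0932), formate dehydrogenase, the last step of methanol oxidation to carbon dioxide, rose from 15074 ± 5846 to 28052 ± 1484 FPKM, 1.86-fold (log2 0.9, SE 0.25, adjusted p = 0.0108). FLD1 (PAS_chr3_1028), the glutathione-dependent formaldehyde dehydrogenase, rose from 6336 ± 1717 to 10329 ± 195.7 FPKM, 1.63-fold (adjusted p = 0.011), and did not pass without BMMY replicate 2 (log2 0.61). PEX13 (PAS_chr2-2_0207), part of the import machinery of peroxisomes and the 1 peroxisome gene listed, was 1.58-fold higher (adjusted p = 0.0177). Its call was lost without BMMY replicate 2 (0.59), BMMY replicate 3 (0.52), maltose replicate 1 (0.65) or maltose replicate 2 (0.64). With equal FPKM sums FLD1 turned to -0.13 and PEX13 to -0.18, while FDH1 was at 0.08 and did not pass. BMMY replicate 1 lay nearest to the maltose libraries here, with 21781 FPKM of FDH1 against 12383 and 11058 in the other BMMY libraries.

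Of the central carbon genes, 2 of 2 glycolysis and gluconeogenesis members and 1 of 1 pentose phosphate members were higher, and 1 of 1 members of the tricarboxylic acid and glyoxylate list was lower. FBP1 (PAS_chr3_0868), fructose-1,6-bisphosphatase of gluconeogenesis, rose from 1313 ± 151.2 to 2186 ± 88.4 FPKM, 1.66-fold (adjusted p = 0.00294). FBA1 (PAS_chr1-1_0319), the aldolase, was 1.61-fold higher (adjusted p = 0.0198), but not past the threshold without BMMY replicate 2 (log2 0.56), BMMY replicate 3 (0.57), maltose replicate 1 (0.62) or maltose replicate 2 (0.69). SHB17 (PAS_chr2-2_0177), a sedoheptulose bisphosphatase by its symbol, was 1.58-fold higher (adjusted p = 0.0239), with the call lost without the same libraries (0.58, 0.51, 0.6 and 0.64). With equal FPKM sums FBP1, FBA1 and SHB17 turned to -0.12, -0.14 and -0.16. IDP2 (PAS_chr2-1_0580), the cytosolic NADP-dependent isocitrate dehydrogenase, fell 3.93-fold from 72.9 ± 25.2 to 18.6 ± 1.34 FPKM (adjusted p = 3.60e-04). BMMY replicate 1 had the highest BMMY value of FBP1, FBA1 and SHB17 and the lowest of IDP2 (45.0 FPKM). The carbon regulator list had 2 members tested, both lower. CAT8 (PAS_chr4_0540), an activator of genes for growth on non-fermentable carbon, was 2.76-fold lower (adjusted p = 0.00212), but at -0.61 with equal medians it did not pass. SFL2 (PAS_chr2-1_0404), 3.74-fold lower (adjusted p = 0.00136), was matched only as a transcriptional repressor, and its annotation names no role in carbon control.

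Oxidative stress genes went both ways: of 5 tested, 3 were higher, 1 was lower and 1 did not pass, with 4 past the threshold when adjusted over the list alone (adjusted Fisher's exact p = 0.674). MXR1 (PAS_chr3_0066), which repairs oxidised methionine in proteins, fell 4.82-fold from 1121 ± 215.2 to 233 ± 31.2 FPKM (adjusted p = 7.42e-05). SRX1 (PAS_chr2-1_0236), sulfiredoxin, and ustS (PAS_chr2-1_0748), a gene known here by similarity, were 1.69-fold and 1.66-fold higher (adjusted p = 0.0197 and 0.0167), and FLD1, given above, was the third. With equal FPKM sums SRX1 turned to -0.07 and ustS to -0.1. SRX1 did not pass without BMMY replicate 2 (0.59), BMMY replicate 3 (0.63) or maltose replicate 2 (0.75), nor ustS without BMMY replicate 2 (0.6) or maltose replicate 3 (0.65). PAS_chr1-4_0659, with no name (given after its value was seen), had means of 147 and 234 FPKM and an adjusted p of 0.0793.

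Of 3 sterol and lipid genes, 1 was higher, 1 was lower and 1 did not pass, and 2 passed when adjusted over the list alone. INO1 (PAS_chr2-2_0113), the enzyme that makes inositol phosphate from glucose 6-phosphate, fell 7.24-fold from 147 ± 28.4 to 20.3 ± 4.3 FPKM (adjusted p = 4.24e-05). FPS1 (PAS_chr1-4_0314), here farnesyl pyrophosphate synthetase of the sterol pathway, was 1.7-fold higher (adjusted p = 0.0172). FPS1 turned to -0.06 with equal FPKM sums and did not pass without BMMY replicate 2 (0.66), BMMY replicate 3 (0.62) or maltose replicate 1 (0.75). SUT2, a putative transcription factor, had an adjusted p of 0.0635. Of 3 metal genes 1 was higher and 2 were lower (adjusted Fisher's exact p = 1), and 3 passed when adjusted over the list alone. FRE3 (PAS_chr4_0240), a ferric reductase, was 2.37-fold higher (adjusted p = 0.00306), and did not pass with equal FPKM sums (0.37). FET4 (PAS_chr2-2_0009), a low-affinity iron transporter, was 3.52-fold lower (adjusted p = 1.51e-04) and zrt1 (PAS_chr3_0516), a zinc transporter, 2.98-fold lower (adjusted p = 0.00143), though zrt1 did not pass with equal medians (-0.64).

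Single genes stood for the remaining lists that had members. PAS_chr1-3_0151, a nucleolar protein for ribosomal RNA processing and the 1 ribosome biogenesis gene, rose from 4.65 ± 0.522 to 14.2 ± 1.88 FPKM, 3.05-fold (adjusted p = 1.40e-04). Gid4 (PAS_chr4_0047), matched to the secretory traffic list through its vesicles, acts in the degradation of gluconeogenic enzymes. It had 173 ± 183.9 FPKM in BMMY and 539 ± 41.8 with maltose, 3.12-fold higher (log2 1.64, SE 0.66, adjusted p = 0.0415). Without BMMY replicate 1 the log2 fold change of Gid4 was 3.01, and with each library left out in turn the adjusted p ran from 2.81e-11 to 0.101. It did not pass without BMMY replicate 2 (1.26), BMMY replicate 3 (1.25), or maltose replicate 1 (1.6), 2 (1.62) or 3 (1.7), nor with equal FPKM sums (0.94). The protease YPS1 (PAS_chr3_0299), a cell surface aspartic protease, was 3.05-fold lower (adjusted p = 1.22e-04). The cohesin subunit psm1 (PAS_chr2-1_0082), from the cell cycle list, was 2.68-fold lower (adjusted p = 0.00156), and did not pass with equal medians (-0.56). From the mating and sporulation list, ADY2 (PAS_chr1-1_0418), an acetate transporter, was 2.63-fold lower (813 ± 52.1 to 309 ± 47.5 FPKM, adjusted p = 2.53e-04).

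The remaining named genes taken by size of change were of mixed function. ATO2 (PAS_chr1-1_0158), a putative ammonia exporter, was 5.91-fold lower (758.5 ± 461.7 to 128 ± 23.5 FPKM, SE of the log2 fold change 0.51, adjusted p = 0.00199), and BMMY replicate 1, at 249.9 FPKM, was far below the other BMMY libraries at 874 and 1151. The genes pfl5 (PAS_chr2-2_0482) and dmoA (PAS_chr1-4_0681), both known here by similarity, were 7.59-fold and 6.83-fold lower (adjusted p = 4.05e-05 and 7.42e-05). The amphiphysin-like gene hob3 (PAS_chr3_0833) was 2.02-fold higher (adjusted p = 0.00379), and did not pass with equal FPKM sums (0.18). Among genes with no name or description (chosen after their values were seen), the largest rises were in PAS_chr4_0058 (114 ± 36.4 to 529.7 ± 54.4 FPKM, 4.64-fold, adjusted p = 1.54e-04) and PAS_chr4_0064 (1465 ± 187.1 to 6394 ± 726.4 FPKM, 4.36-fold, adjusted p = 4.05e-05). The largest falls in such genes were in PAS_chr3_0016 and PAS_chr4_0357, at -2.65 and -2.64 on the log2 scale (adjusted p = 2.53e-04 for both). No listed gene matched 14 of the 30 lists: maltose and alpha-glucoside use, sugar transport, oxidative phosphorylation, ribosomal proteins, mitochondrial translation, folding in the endoplasmic reticulum, glycosylation, proteasome, heat shock, cell wall, fatty acid oxidation, storage carbohydrates, glycerol, and mitochondrially encoded genes. As the table holds selected genes, this gives no value for those lists.

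**Figure D3:**
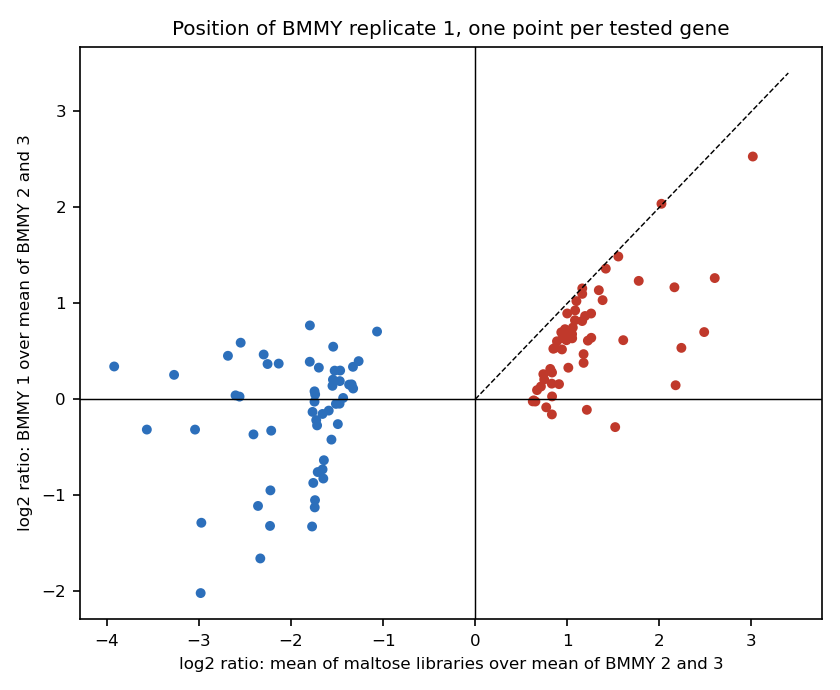
Each point is 1 of 112 tested genes, with the log2 ratio of the maltose mean to the mean of BMMY replicates 2 and 3 on the x axis and that of BMMY replicate 1 to the same mean on the y axis, and the dashed line where both are equal. Genes with positive fold changes (red) lie mostly above 0, 47 of 56 being above both other BMMY libraries, while lower genes (blue) lie on both sides, 23 of 56 being above both.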

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

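The alternatives with limma on log2(FPKM + 1), the recovered scaling, TMM and DESeq2 were chosen after the data were examined, and so were, for the lists and named genes, equal FPKM sums, the filter of 10 and no trend, as well as the stricter thresholds for the lists alone and no filter for the named genes alone. The lower genes numbered 56, and did so with each library left out, with equal FPKM sums, TMM, DESeq2 and both stricter thresholds. They numbered 31 with a mean FPKM of at least 10, which tests 83 genes, and 35 with equal medians. Selection bears on this, since no tested fall was smaller than -1.34 on the log2 scale, while rises went down to 0.63. Equal FPKM sums and TMM also shift all fold changes downward. The steady number of lower genes was therefore largely set in advance. The genes higher with maltose, 49, moved more: 7 (of 63 in all) with equal FPKM sums, 13 (of 69) with TMM, 13 (of 69) when a 2-fold change was also asked for, and 27 at an adjusted p of 0.01. Scaling sets how many rises pass, by its construction, since each shifts all genes of a library together. Leaving out 1 library at a time gave 85 to 112 genes in all, 29 to 56 higher and 56 to 56 lower. The calls made without BMMY replicate 1 (112) held all 105, with 7 more. The lowest, 85, came without BMMY replicate 2.

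Of the 4 lists tested for direction, 1 passed, the amino acid list, and this call was lost (0 passed) in 9 of 20 alternatives. In 6 of these, the list had 3 higher members in place of 1, since ARO7 and GLY1 then passed: without BMMY replicate 1, with limma at either pseudocount, the recovered scaling, DESeq2 size factors (adjusted p = 0.119 in each) and the DESeq2 test (0.12). With equal medians 3 members were higher too, against 11 lower, and the call was kept (0.00702). In the other 3 no member was higher, and few other genes were: equal FPKM sums (0.329), TMM (0.104) and a 2-fold change (0.209). With equal FPKM sums and with TMM no other list could be tested, so the adjustment there changed nothing. With 1 library left out, 0 to 1 lists passed. Where the call was kept, the adjusted p lay between 8.31e-04 and 0.0389. A set test with an estimated correlation was not run, since it needs most genes of the genome.

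With the replicate number as a block, 105 genes passed, 104 of them shared, with RIB3 (named after its value was seen) lost and 1 gained. To look for pairing, the log2(FPKM + 1) values of each library were taken as deviations from the mean of its own group. The correlations of these deviations between same-numbered libraries were -0.201, 0.001 and 0, and no library correlated best with its own number. Within a group the deviations of a gene sum to 0, so the correlations are not free of each other. The labels state no shared batch, and the numbers were not used as pairs.

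Of the 40 named genes, 40 kept their call without BMMY replicate 1, 29 without BMMY replicate 2, 33 without BMMY replicate 3 and 35 without each maltose replicate. With equal medians 37 kept it, with a mean FPKM of at least 10 all 33 tested, with TMM 28, and with equal FPKM sums 23, where 9 turned: FLD1 (-0.13), PEX13 (-0.18), FBP1 (-0.12), FBA1 (-0.14), SHB17 (-0.16), GAP1 (-0.21), SRX1 (-0.07), ustS (-0.1) and FPS1 (-0.06). All 40 kept it with limma, the block, the recovered scaling, no filter, no trend and DESeq2. The lowest count of a listed gene in a library was 11, and how many values depth limits was not tested.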

Other observations

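The pathway tests, the tests of the 3 patterns and the splits were chosen after the results had been seen, and so were the genes named in the next paragraphs. The edgeR test itself was set before the data were examined, while its values for these genes under other scalings were added afterwards.

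Some genes with annotated roles in sulfur and methionine metabolism were lower with maltose. MET17 (PAS_chr4_0330), the sulfhydrylase that builds sulfide into homocysteine, was 4.28-fold lower (111.0 ± 36.9 to 25.9 ± 7.19 FPKM, SD, n = 3, adjusted p = 3.85e-04 in edgeR's quasi-likelihood test). CysA (PAS_chr2-1_0383), homoserine acetyltransferase, was 3.84-fold lower and MET10 (PAS_chr4_0369), a sulfite reductase subunit, 3.15-fold lower (adjusted p = 8.76e-05 for both). MET6 (PAS_chr2-1_0160), methionine synthase, was 2.53-fold lower (adjusted p = 0.00481) and MUP1 (PAS_chr2-1_0351), a methionine permease, 2.66-fold lower (adjusted p = 3.90e-04). A neighbouring pair of genes with the symbol dmoA, named for a monooxygenase of organic sulfur compounds, was 6.83-fold and 3.1-fold lower. With equal medians MET6 (-0.39 on the log2 scale) and MUP1 (-0.46) did not pass, while MET17 (-1.13), CysA (-0.99), MET10 (-0.75) and the dmoA genes (-1.82 and -0.7) did. These genes were gathered by eye from a list selected for change, with no enrichment test, so a change of the pathway as a whole is not shown.

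Genes similar to the acetate and ammonia transporters of the ADY2 family went in both directions. PAS_chr1-1_0418 (ADY2) and PAS_chr1-1_0158 (ATO2) were 2.63-fold and 5.91-fold lower. PAS_chr1-1_0378 (ADY2) was 1.63-fold higher (593.9 ± 93.6 to 966.0 ± 45.8 FPKM, adjusted p = 0.00741) and PAS_chr2-1_0874 (ADY2) 1.81-fold higher (511.8 ± 35.8 to 926 ± 57.0 FPKM, adjusted p = 0.00173), but with equal FPKM sums they turned to -0.16 and -0.01. Reads shared among these similar genes were not tested. The most abundant listed gene was TMA10 (PAS_chr4_0407), a ribosome-associated protein, at 28250.0 ± 1849.8 FPKM in BMMY and 43989 ± 2872 with maltose (1.56-fold, adjusted p = 0.00286), which turned to -0.23 with equal FPKM sums. By the pathway annotation in the table, 4 of 4 thiamine genes and 4 of 4 methane metabolism genes were higher, but neither passed Fisher's exact test over 6 pathways (p = 0.0443, adjusted p = 0.0886 for each). Cofactor synthesis had 7 higher and 1 lower (Fisher's exact p = 0.024, adjusted p = 0.0886). Carbon metabolism, with 4 higher and 1 lower (adjusted Fisher's exact p = 0.219), and glycolysis, with 3 higher and 0 lower (0.147), did not pass either. Arginine and proline metabolism held CAR1 (PAS_chr4_0684), CAR2 and ALD5. It had 1 higher and 2 lower and did not pass. The annotation did not place CAR1 (PAS_chr2-2_0288), PUT1 or PUT2 (PAS_chr2-2_0496) in this pathway. All of these were lower, at -4.04, -3.47 and -1.75 on the log2 scale, so the test does not cover them.

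BMMY replicate 1 lay toward the maltose libraries more for genes with positive fold changes than for lower ones. On a scale from 0 at the other BMMY libraries to 1 at the maltose mean, its median position was 0.43 for the former (quartiles 0.15 and 0.64) and 0.0 for the latter (-0.3 and 0.42), where ATO2, IDP2 and SFL2 were among those toward maltose. RNA of a maltose culture in that library, or a wrong label, would move both alike, and the difference of 0.43 (95% bootstrap interval 0.17 to 0.68, 10000 resamples of genes, which are not independent) argues against either as the whole cause. A difference in culture state or library preparation stays open, and no biological explanation was tested.

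The deposited log2 fold changes lay above the FPKM ratios by a nearly constant amount, and the recovered scaling over depth differed between maltose and BMMY libraries by -0.36 on the log2 scale (-0.18 to -0.46 between single libraries). The larger share of counts taken by the listed genes predicts a shift of -0.11 (-0.14 to -0.08), which argues against that share as the whole cause. Genes outside the list were not analysed here, so what gives the rest stays open, and with it whether the smaller rises are rises against most other transcripts. No biological explanation was tested.

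Listed genes lay next to each other in the genome order of ASM2700v1 more often than random genes. There were 11 adjacent pairs, against 2.6 on average in 10000 random draws (permutation p = 3.00e-04), which argues against random placement. Of the 11 pairs, 9 changed in the same direction, against 5.4 on average when directions were shuffled (permutation p = 0.0314), among them THI20 with thi4 and PAS_chr4_0064 with THI5, while TPN1 and ARO8 went opposite ways. Reads counted for both of 2 overlapping neighbours stay open, since the strand setting is not given in the sources used here, and shared regulation was not tested.

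The 6 libraries can be split 3 and 3 in 10 ways. The real split gave 105 genes and the highest of the others 0, with 1 split as large as the real one, itself. The genes had been selected on the real split, so it was bound to give the most, and the comparison tests nothing. So few splits cannot give a share under 0.05.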
